A study of Mus musculus with 4 samples.

How the data were processed

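Group 2 innate lymphoid cells (ILC2s), lymphocytes of barrier tissues that secrete type 2 cytokines without an antigen receptor, were sorted from lungs of BALB/c mice. Per the labels' protocols they were cultured for 18 hours with an isotype control antibody or with an antibody against CD226, a costimulatory receptor. The dose given is 5 µg/mL, and its wording leaves open whether it also applies to the isotype control. The series' design text instead speaks of treated mice, and the treatment column of the deposited table calls the controls PBS; the labels of the samples were followed here. The labels give 2 libraries per group. They do not say whether the 2 libraries of a group came from separate mice or separate cultures, so p-values measure only the spread between these libraries, which may be technical.

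Per the labels' protocols, which may misstate the unit, cDNA was made from 10 pg of RNA per sample with a low-input kit (SMARTer Ultra Low Input v3) and sequenced on a NextSeq 500. Per the submitters' processing notes, STAR 2.7.8, Partek 10.0 and DESeq2 (no version given) were used with genome build mm10. The counting tool, the gene annotation and the treatment of strand are not given in the sources used here. Reads from a gene and from a gene that overlaps it on the other strand, or from a near-identical copy, therefore cannot be told apart.

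The authors deposited 1 normalised signal value per gene and library, for 17187 genes. Of each library's values between 0.5 and 1000 steps (12769 to 13599 genes), between 73.5% and 75.1% were whole multiples of a single step (tolerance 0.02 of a step), and the step differed between libraries. Larger values were not checked. The rest were fractional. The values are therefore treated as estimated read counts divided by 1 factor per library. Because whole reads were not obtained for nearly all genes, no count model was run, and depth is given only as an estimate, the library's total divided by its step. The step also gives a floor for a value of 0, that of 3 reads, which was between 2.32 and 3.32 normalised reads per library and covers counting error only. Reads from an amplified low-input library are not independent molecules, so counting error understates the error of genes with few reads. With 839 gene columns checked singly against the unit, the remaining columns of the table were taken to hold the same quantity.

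Genes with a mean value of 10 or more over the 4 libraries were tested (13010 genes). The test was limma 3.58.1 in R 4.3.3, with a mean-variance trend, on log2(value + 1), without a replicate term, two-sided, with Benjamini-Hochberg adjustment. The fit has 2 residual degrees of freedom and 5.81 prior degrees of freedom. Fold changes are on the log2(value + 1) scale, which understates the change of genes with few reads. Fixed gene lists were compared with all other genes tested by limma's camera with a preset inter-gene correlation of 0.01, adjusted over the 34 lists that had at least 3 genes tested, of 38 fixed. An estimated correlation and limma's fry, which asks whether a list's own genes move one way on balance, were run beside it. Single genes of a list were also adjusted over the list alone. That adjustment is not corrected for the 34 lists, so a gene can pass it in some list by chance. For single genes an exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333, so p-values of genes come from limma.

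The gene lists, the design and the rule for naming genes were fixed before the data were examined. The rule names Cd226; of genes with a mean of 50 or more and groups that do not overlap, the 10 largest rises and falls past an adjusted p of 0.05, filled up with those of smallest unadjusted p; up to 4 genes of smallest p in each list; and 8 cytokine and 6 identity genes of ILC2s whatever their result. Genes named outside the rule are marked as chosen after their values were seen. Gene positions and transcript lengths come from GENCODE M21 on GRCm38, the assembly that mm10 denotes. A length was found for 97.5% of the genes in the table.

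The same steps were tested on simulated values for the anti-CD226 comparison with 13010 genes. Of 100 genes changed 2-fold, 58.0% were recovered at an adjusted p below 0.05, and of 100 changed 4-fold, 84.0%, with 17 false calls. In this single simulation the false calls were a larger share of all calls than the 0.05 at which the threshold aims. A simulated list of 30 genes shifted by 0.5 on the log2 scale was called and 0 of 30 unshifted lists were. The simulated noise was drawn separately for each gene, without a length trend or differences shared by the genes of a list. It therefore does not check the preset correlation, and recovery in the real data may differ. Alternatives covered the pseudocount, the filter, 4 other scalings, the variance prior and trend, a replicate block and leaving out each library. Added after seeing the data were crossed replicate pairs, removal of each library's trend with transcript length (loess, span 0.3), that removal together with the block, and list medians for each anti-CD226 library alone. Figures were drawn with matplotlib 3.10.9.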

Results

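The transcriptomes of 4 libraries were compared, 2 of cultured lung ILC2s given an isotype control antibody and 2 of ILC2s given anti-CD226. The series' title names CD226 blockade, the effector function of ILC2s and airway hyperreactivity, so the comparison asks which transcripts of ILC2s differ when CD226 is bound by an antibody. The estimated depth was 12433713 and 17847334 reads for isotype replicates 1 and 2, and 13521417 and 12474190 reads for anti-CD226 replicates 1 and 2. Between 16602 and 16847 genes had a value above 0 in a library. Values below are normalised read counts, and errors are SDs over the 2 libraries of a group (n = 2).

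All 4 libraries carried the transcripts of activated ILC2s. Il5, the cytokine that sustains eosinophils, was the gene with the third highest mean after Actb and Tmsb4x, and made up between 0.494% and 0.708% of a library's signal. Gata3, the transcription factor of the type 2 lineage, had 14004 ± 274 in isotype and 16110 ± 1697 in anti-CD226 libraries. Il1rl1, the receptor for IL-33, had 8612 ± 555 and 8673 ± 515, a log2 difference of 0.01 whose sign turned under upper quartile scaling and quantile normalization. Of the 27 ILC2 identity genes tested, 16 were higher and 11 lower, with a median log2 fold change of 0.09, and 0 passed with adjustment over all genes or adjusted over the list alone. Rora had the smallest p among Gata3, Rora, Il1rl1, Il7r, Icos and Klrg1, with 3461 ± 106 against 4396 ± 663 (limma, adjusted p = 0.98).

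Cd226 itself, on chromosome 18 from 89176967 to 89272229 (GRCm38, plus strand), had 992 ± 70.7 in isotype and 993 ± 10.9 in anti-CD226 libraries. The log2 difference was 0.0040 with a standard error of 0.17, and its sign turned under 3 of the other scalings (total, upper quartile and quantile). Of the 8 genes tested on the list of CD226 and its related receptors and ligands, 6 were higher and 2 lower, with 0 past either adjustment. The CD226 ligand Pvr had 88.9 ± 5.54 against 138 ± 49.6 and the ligand Nectin2 had 8.94 ± 4.83 against 19.5 ± 8.85. The receptor Cd96, which shares Pvr as a ligand, had 85.6 ± 13.3 against 118 ± 28.2. For this list camera gave an adjusted p of 0.43.

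No gene of the 13010 tested passed limma's adjusted p of 0.05, and the smallest adjusted p was 0.982. At an unadjusted p below 0.05 there were 308 genes, 202 higher and 106 lower in anti-CD226, where chance alone gives 650.5, and 237 of them differed by at least 1.5-fold (154 higher, 83 lower). The groups did not overlap in 26.8% of genes, where chance gives 33.3%. Replicates were no closer to each other than some libraries of different groups. Pearson's r across genes, which are not independent replicates, was 0.986 between the isotype libraries, 0.973 between the anti-CD226 libraries and 0.987 between isotype replicate 2 and anti-CD226 replicate 1. The lowest, 0.968, was between isotype replicate 2 and anti-CD226 replicate 2. The count of calls depended on single libraries. It was 1633 without anti-CD226 replicate 1, 53 without anti-CD226 replicate 2, 12 without isotype replicate 1 and 17 without isotype replicate 2, fits in which the lone library is assumed to vary like the other group.

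The genes with the smallest p whose groups stood apart were Il9 among the lower ones and Cul3 among the higher ones, and neither passed the adjustment over all genes (adjusted p = 0.98 for each). Cul3, a scaffold of ubiquitin ligases, had 342 ± 16.6 in isotype and 884 ± 173 in anti-CD226 libraries (log2 fold change 1.35, standard error 0.20). Slk, a serine/threonine kinase of the cytoskeleton, had 927 ± 190 against 2098 ± 125. Rcc2, a regulator of chromosome condensation, had 3535 ± 665 against 6365 ± 467. Cotl1, which binds actin, had 2738 ± 76.5 against 5014 ± 1020. The subunit of G proteins encoded by Gna12 had 373 ± 137 against 819 ± 139. Usp31 had 175 ± 5.63 against 353 ± 49.4, Zmiz2 had 661 ± 56.9 against 1151 ± 52.4 and Selenon had 54.3 ± 20.49 against 144 ± 26.2. The lower genes besides Il9 were Gm5537, Eml2, Xpr1, Gm45713, Gm9888, Txnl4b, Mon2, Pot1b and Vapb, between 1.51-fold and 2.01-fold lower. Gm5537 is annotated as a processed pseudogene and Gm9888 as antisense, so the origin of their reads is uncertain. The phosphate exporter Xpr1 had 577 ± 57.5 against 330 ± 106, and Eml2, which binds microtubules, had 516 ± 18.7 against 270 ± 118.

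The cytokine genes of ILC2s were lower in anti-CD226 libraries as a group, and Il9 differed most. Of the 18 effector genes tested, 14 were lower and 4 higher, with a median log2 fold change of -0.21 (camera, adjusted p = 0.0064; adjusted p = 0.91 with an estimated correlation). Il9, which acts on mast cells and on ILC2s themselves, had 112 ± 24.2 in isotype and 25.03 ± 0.452 in anti-CD226 libraries. The SD of 0.452 is below the value of 1 read, 1.03 and 1.10 in anti-CD226 replicates 1 and 2, so counting error exceeds it. The log2 fold change of Il9 was -2.10 with a standard error of 0.31, past the threshold when adjusted over the list alone (adjusted p = 0.0025) but not over all genes (adjusted p = 0.98). It lies on chromosome 13 from 56479277 to 56482246 on the minus strand (GRCm38). The count adjusted over the list alone was 1 lower and 0 higher, and that over all genes was 0. Il13, the cytokine of mucus production and airway reactivity, had 3096 ± 457 against 1823 ± 1276, the 2 anti-CD226 libraries standing at 2725 and 921. Il5 had 96333 ± 1870 against 76648 ± 12422 (limma, adjusted p = 0.98). Il13 and Il5 missed both adjustments, as did their neighbours on chromosome 11, Il4 with 122 ± 21.5 against 109 ± 39.9 and Csf2 with 4904 ± 395 against 4725 ± 1249. Il10 had 136 ± 25.1 against 104 ± 24.3, Il6 had 26.1 ± 8.46 against 19.7 ± 0.196, and Areg, a ligand of the EGF receptor, had 790 ± 15.1 against 751 ± 194. The anti-CD226 SD of Il6 is also below the value of 1 read. The shift of the list rests in part on anti-CD226 replicate 2: without it the median was -0.12 (camera, adjusted p = 0.059). With each library's trend with transcript length removed, the median was -0.13 and the adjusted p 0.043. With no filter on low genes the median was -0.10 and the adjusted p 0.50.

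Il22, a cytokine of group 3 innate lymphoid cells (ILC3s), went the other way. It had 35.1 ± 7.21 in isotype and 96.8 ± 21.4 in anti-CD226 libraries, a log2 fold change of 1.44 with a standard error of 0.32. It passed when adjusted over the list alone (adjusted p = 0.0099), without correction over the lists, and missed over all genes (adjusted p = 0.98). Of the 5 ILC3 genes tested, 3 were higher and 2 lower, and camera gave an adjusted p of 0.67.

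**Figure D1:**
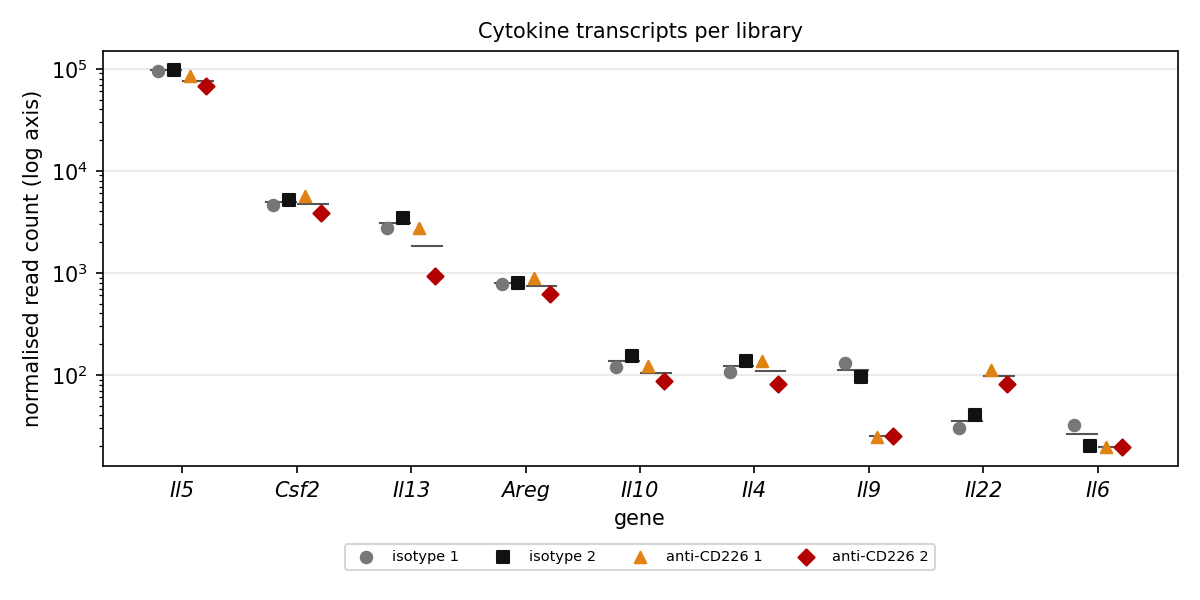
Normalised read counts (log axis) of 9 cytokine genes, with 1 point per library and a bar at the mean of each group. Il9 stands at 129 and 95.03 in the isotype libraries and at 24.7 and 25.3 in the anti-CD226 libraries, Il22 at 30.0 and 40.2 against 112 and 81.7, and Il13 at 921 in anti-CD226 replicate 2 alone.

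Transcripts of macrophages were higher in the anti-CD226 libraries. Of the 6 genes tested on the list of macrophage and monocyte markers, 5 were higher, with a median log2 fold change of 0.65 (camera, adjusted p = 0.0026; adjusted p = 0.91 with an estimated correlation). The median was 0.39 with no filter on low genes and 0.90 with a filter of 50. No gene of this list passed either adjustment, the smallest being Lyz2, lysozyme, with 2.04 ± 1.80 against 30.0 ± 30.8 (adjusted p = 0.068 adjusted over the list alone). Chil3, a chitinase-like protein abundant in lung macrophages, stood at 19.9 and 0 in the isotype libraries and at 16.5 and 784 in the anti-CD226 libraries. The lysosomal Cd68 had 37.0 ± 2.31 against 71.9 ± 23.0, and the protease Ctss had 210 ± 28.4 against 258 ± 44.0. Mmp12, the macrophage elastase on chromosome 9 from 7344381 to 7369499, stood at 34.3 and 2.32 in isotype and at 168 and 678 in anti-CD226 libraries. Its log2 fold change was 4.97 with a standard error of 1.04 (limma, adjusted p = 0.98). Without anti-CD226 replicate 2 the adjusted p of the list was 0.068 and its median 0.52. Other members of the list, chosen after their values were seen, went different ways. Apoe and Csf1r were at or below 14.4 in every library. Itgam stood at 1.11 and 0 in isotype libraries against 19.6 and 18.7, and Mpeg1 at 0 and 0 against 4.12 and 16.5.

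The 30 genes tested for the uptake and oxidation of fatty acids were not shifted as a list, with 11 higher and 19 lower and a median of -0.03 (camera, adjusted p = 0.85). Cd36, a fatty acid translocase, had 3.32 ± 4.69 against 69.9 ± 30.5 and passed when adjusted over the list alone (adjusted p = 0.038), the only gene of the 30 to do so. Its isotype values, 6.63 and 0, rest on few reads, and whether its reads came from ILC2s was not tested. Lpl, lipoprotein lipase, had 11.3 ± 13.8 against 104 ± 72.0 and missed (adjusted p = 0.083 adjusted over the list alone). Of the 8 dendritic cell genes tested, Itgax, which encodes the integrin CD11c and is also carried by alveolar macrophages, had 0.553 ± 0.781 against 30.4 ± 22.5. It was the only gene of that list to pass when adjusted over the list alone (adjusted p = 0.017), and the list had a median of -0.05 (camera, adjusted p = 0.62). Over all genes these 3 had an adjusted p of 0.98 in limma's test.

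**Figure D2:**
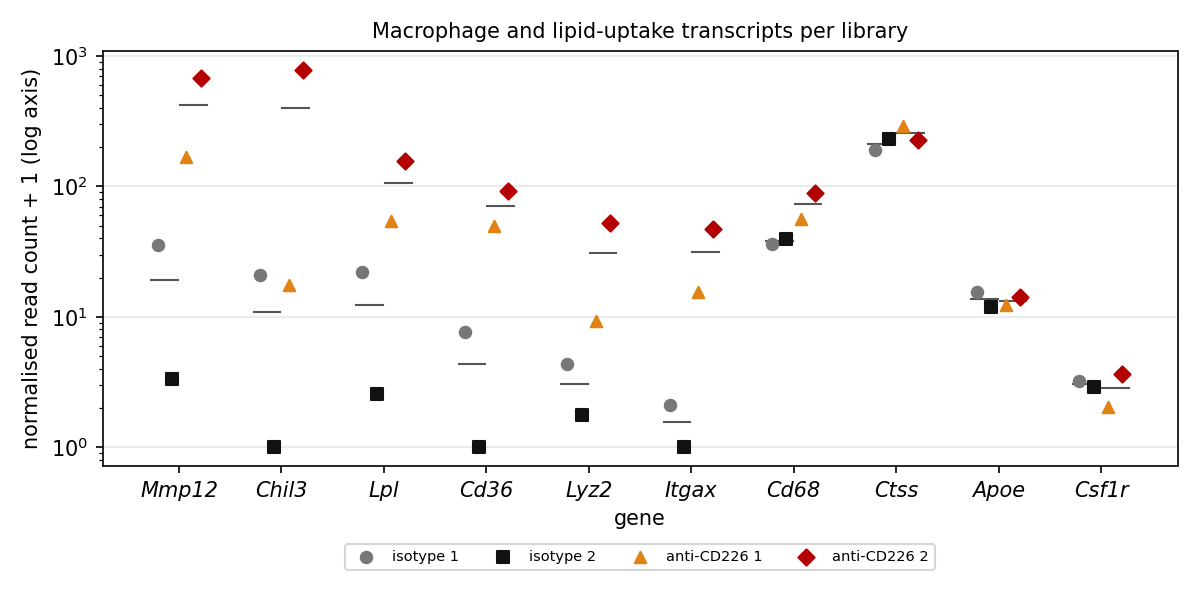
Normalised read counts plus 1 (log axis) of 10 genes of macrophages and lipid uptake, with 1 point per library and a bar at the mean of each group. Mmp12, Lpl, Cd36, Lyz2, Itgax and Cd68 lie higher in both anti-CD226 libraries than in both isotype libraries. Chil3 stands at 784 in anti-CD226 replicate 2 alone, and Ctss, Apoe and Csf1r overlap between groups. Apoe and Csf1r were chosen after their values were seen.

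Markers of other cell types gave no shifted list. Of 9 mast cell and basophil genes, 7 were lower and 2 higher, with a median log2 fold change of -0.17 (camera, adjusted p = 0.59). Without anti-CD226 replicate 2 this list was called lower, with a median of -0.35 (camera, adjusted p = 0.010). The mast cell carboxypeptidase Cpa3 had 92.2 ± 11.6 against 50.5 ± 19.0, the basophil protease Mcpt8 had 34.5 ± 0.362 against 17.1 ± 2.33, and the transcription factor Gata2 had 9.44 ± 0.851 against 23.9 ± 4.12. None of these 3 passed either adjustment. Mcpt8 rests on 31 and 45 reads in isotype and on 15 and 17 in anti-CD226 libraries, so counting error exceeds its isotype SD. Of 10 T cell genes, 4 were higher and 6 lower (median -0.22, camera adjusted p = 0.61); Trdc, the constant region of the delta chain, which ILC2s can also transcribe, had 40.4 ± 10.1 against 79.7 ± 30.0. The lists of natural killer cells, epithelium, endothelium and fibroblasts had adjusted p of 0.62, 0.88, 0.59 and 0.85. Markers of B cells, neutrophils, eosinophils and erythroid cells had 2, 1, 2 and 1 genes tested and were too few for camera.

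Ribosomal protein genes and nuclear genes of oxidative phosphorylation were lower in anti-CD226 replicate 2 and not in anti-CD226 replicate 1. All 80 ribosomal protein genes tested were lower on average, with a median log2 fold change of -0.33 (camera, adjusted p = 2.8e-15; adjusted p = 0.91 with an estimated correlation). Against the isotype mean, the median was -0.75 in anti-CD226 replicate 2 and 0.11 in anti-CD226 replicate 1. Without replicate 2 the list was called higher (camera, adjusted p = 0.010). Rps3 stood at 7161 and 8912 in isotype libraries and at 7906 and 3641 in anti-CD226 libraries. Of 52 genes of oxidative phosphorylation, 49 were lower and 3 higher (median -0.21, camera adjusted p = 2.6e-07; adjusted p = 0.91 with an estimated correlation). Without anti-CD226 replicate 2 that median was 0.09 (camera, adjusted p = 0.071). Atp5e, a subunit of the ATP synthase, stood at 1680 and 2068 in isotype libraries and at 1834 and 723 in anti-CD226 libraries. No gene of these lists passed either adjustment. Ribosomal protein genes made up 2.43% and 2.99% of the signal in isotype libraries and 2.83% and 1.60% in anti-CD226 libraries. The 13 mitochondrially encoded genes had a median of -0.07 (camera, adjusted p = 0.57), and among them mt-Nd3 had 578 ± 148 against 317 ± 149. Without isotype replicate 1 that list was called lower, with a median of -0.28 (camera, adjusted p = 7.2e-05), without isotype replicate 2 its median was 0.17 (adjusted p = 0.37), and with the length trend removed it was 0.05 (adjusted p = 0.99). They made up 0.445% and 0.672% of the signal in isotype libraries and 0.524% and 0.480% in anti-CD226 libraries.

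The libraries differed in how a gene's deviation from its mean followed transcript length. Over 10176 genes, Spearman's rho between the 2 was 0.02 in isotype replicate 1, -0.49 in isotype replicate 2, -0.38 in anti-CD226 replicate 1 and 0.51 in anti-CD226 replicate 2. Each deviation is taken from the mean of the same 4 libraries, so a rise in some libraries forces a fall in others. The values of rho are therefore relative and do not show a library's own trend. In the decile of shortest transcripts, the median deviation was 0.15 in isotype replicate 2 and -0.23 in anti-CD226 replicate 2. The annotated transcripts of Rps3, Rps21, Atp5e and Ndufa2 are 952, 394, 421 and 572 bases long, against a median of 596 bases in the decile of shortest and 5951 in that of longest transcripts. Some genes with higher means in anti-CD226 are long, such as Usp31, Sos1 and Pik3ca with 10198, 8436 and 6689 bases. Others are short, such as Cotl1 and Akt1 with 1520 and 1102.

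**Figure D3:**
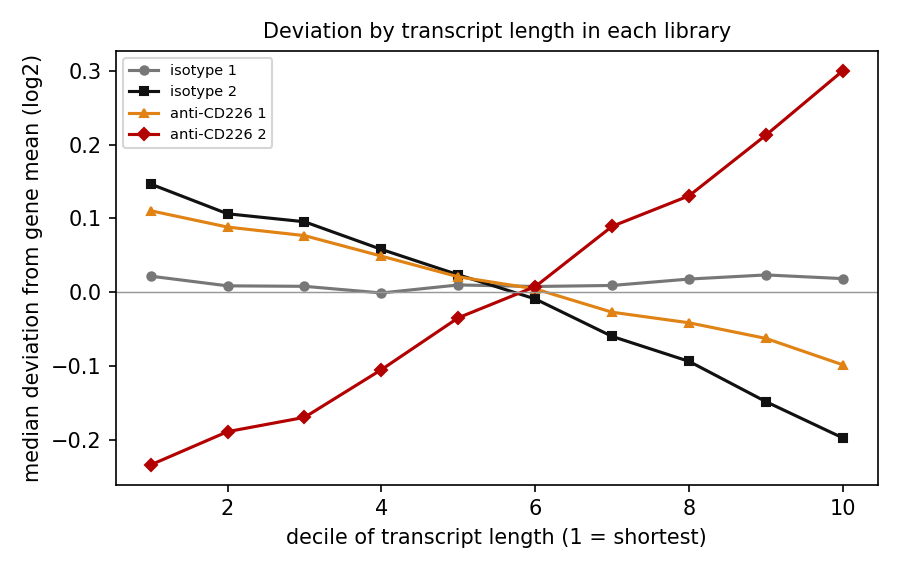
Median deviation of genes from their own mean over the 4 libraries (log2, vertical axis) in each decile of transcript length (horizontal axis), 1 line per library. From the shortest to the longest decile, anti-CD226 replicate 2 goes from -0.23 to 0.30 and isotype replicate 2 from 0.15 to -0.20, while isotype replicate 1 stays between -0.00 and 0.02.

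Signalling genes that can act below costimulatory receptors gave no shifted list. Of 29 genes of the PI3K, AKT, mTOR and FOXO list, 19 were higher and 10 lower (median 0.09, camera adjusted p = 0.45). Pik3ca, the catalytic subunit of PI3-kinase, had 574 ± 44.1 against 932 ± 227, Akt1 had 3863 ± 809 against 5845 ± 599, Sesn1, a FOXO and p53 target, had 405 ± 11.4 against 528 ± 10.4, and the mTORC1 inhibitor Ddit4 had 766 ± 75.1 against 500 ± 224. Of 28 early response genes of the MAPK and AP-1 list, 15 were higher and 13 lower (median 0.08, camera adjusted p = 0.45). The feedback inhibitors Spred1 and Spry1 had 314 ± 19.9 against 489 ± 31.8 and 608 ± 4.02 against 876 ± 284. The transcription factors Fosl1 and Egr2 had 125 ± 37.2 against 193 ± 25.1 and 9.72 ± 5.01 against 23.0 ± 6.38. Of 25 NF-kB targets, 13 were higher and 12 lower (median 0.02, camera adjusted p = 0.61), with Tnfaip3 at 242 ± 29.7 against 371 ± 84.1 and Rel at 86.4 ± 10.7 against 143 ± 50.5. Of 31 genes of proximal antigen receptor signalling, 19 were higher and 12 lower (median 0.07, camera adjusted p = 0.59). Among them the exchange factor Sos1 had 719 ± 68.8 against 1198 ± 174 and the adaptor Lat 775 ± 64.5 against 536 ± 35.6. None of these genes passed either adjustment. With the length trend removed, the median was 0.02 for the PI3K list and 0.04 for the MAPK list. It was 0.03 for NF-kB targets and 0.01 for antigen receptor signalling.

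Metabolic, stress and cell cycle lists were not shifted either. Camera's adjusted p was 0.85 for glycolysis, 0.85 for sterol and fatty acid synthesis, 0.67 for the unfolded protein and ATF4 response, 0.45 for antioxidant genes, 0.59 for apoptosis regulators, 0.61 for p53 targets, 0.85 for S phase, 0.62 for G2 and M phase, 0.85 for heat shock and 0.67 for nuclear-retained RNA. Atf5, a target of the integrated stress response, had 29.7 ± 2.86 against 11.2 ± 2.80, and Vldlr, also induced by it, had 13.4 ± 1.79 against 30.1 ± 8.34. The 30 interferon-stimulated genes tested had a median of -0.07 (camera, adjusted p = 0.62), and among them the guanylate-binding Gbp5 had 97.5 ± 20.6 against 50.7 ± 17.1. For cytokine receptors, costimulatory receptors and chemokine receptors, camera's adjusted p was 0.61, 0.61 and 0.85. No gene named here passed either adjustment. The lists of antigen receptor signalling and antioxidant genes passed camera only without anti-CD226 replicate 1 (adjusted p = 0.036 and 0.040).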

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

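The crossed pairs, the removal of the length trend and list medians by library were chosen after seeing the data. Over 18 settings, 68 named genes gave 1214 values, of which 1194 kept their direction and 100 passed an adjusted p of 0.05 that they had missed. The count of 0 genes in limma's test (308 at an unadjusted p below 0.05) also held under both pseudocounts, both filters, 4 scalings, a robust prior, no variance trend and the length correction. The replicates share only a number. With a replicate block 20 genes passed and the 4 lists kept their calls, and with the length trend also removed 4 genes passed (Gpnmb, Mmp12, Cd36 and Cul3). Il9 was among the 20 genes but not among the 4. The block leaves fewer residual degrees of freedom, so its p-values lean on the variance of other genes. With the block alone the standard error of Mmp12 was 0.38, against 1.04 without it. Chil3 passed with the block, although it was at 16.5 in anti-CD226 replicate 1 and at 19.9 in isotype replicate 1. The calls of the block are therefore weak evidence. The replicate differences of the 2 groups correlated at -0.24, so crossed pairs were tried, which called 61 genes and put 390 at the unadjusted p and fold. Leaving out single libraries gave between 12 and 1633 genes. In these fits the log2 fold change of Il9 ranged from -2.32 to -1.88 and that of Mmp12 from 3.26 to 6.67. Their p-values are not given, because a lone library shows no spread of its group.

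The 237 genes at an unadjusted p below 0.05 and 1.5-fold became 393 with no filter, 123 with a filter of 50 and 394 with no variance trend, and between 164 and 1888 with a library left out. Of the 4 shifted lists, 0 passed with an estimated correlation and 0 with fry. The medians stay as in camera there, and the p-values do not. They were -0.33 for ribosomal proteins (adjusted p 0.91 and, with fry, 0.88), -0.21 for oxidative phosphorylation (0.91 and 0.88), -0.21 for effector cytokines (0.91 and 0.77) and 0.65 for macrophage markers (0.91 and 0.81). The effector median was -0.10 with no filter (adjusted p = 0.50). With a library left out, between 2 and 6 lists passed, and medians ranged from -0.75 to 0.11 for ribosomal proteins, -0.531 to 0.0928 for oxidative phosphorylation, -0.35 to -0.10 for effector cytokines and 0.521 to 0.999 for macrophage markers. The sign of the first 2 turned without anti-CD226 replicate 2. The cause was not tested for the other changes.

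Of the named genes, 8 changed sign in at least 1 setting. Cd226 was at -0.0033 with total, -0.0219 with upper quartile and -0.0192 with quantile scaling. Il1rl1 was at -0.0156 and -0.0111 with the latter pair and, with the length trend removed (with or without the block), at -0.0345, where Csf2 was at 0.0263. With a library left out, the ranges were -0.0688 to 0.0767 for Cd226, -0.0554 to 0.0761 for Il1rl1, -0.59 to 0.17 for Il4, -0.35 to 0.20 for Csf2, -0.36 to 0.17 for Areg, -0.563 to 0.0184 for Klrg1, -1.31 to 0.0070 for Rps21 and -1.08 to 0.0601 for Ndufa2. The edgeR and DESeq2 alternatives were not run, because whole reads were not obtained from the values. Depth limits genes such as Lyz2, Itgax and Chil3, which stand at or below 3 reads in at least 1 isotype library.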

Other observations

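The comparison of splits, the tests on the 3 patterns that follow it and the genes of this paragraph and the next were chosen after the values were seen. Values of 6 single genes, Ahr, which encodes the aryl hydrocarbon receptor, and 5 genes it is known to induce, are given without a test of them as a group. Cyp1a1 was at 0 and 10.8 in the isotype libraries, 170 in anti-CD226 replicate 1 and 0 in replicate 2. Cyp1b1 was at 7.74 and 3.09 against 78.2 and 18.7, and Tiparp at 877 and 816 against 1993 and 857. Ahrr, the repressor of the receptor, was at 166 and 117 against 249 and 230, higher in both anti-CD226 libraries as Il22 was. Ahr itself was at 472 and 362 against 357 and 528, and Nqo1 at 1337 and 1445 against 2031 and 1174. In limma's test none of these 6 passed (adjusted p between 0.98 and 0.99). With a replicate block Cyp1b1 passed (adjusted p = 0.030), and without anti-CD226 replicate 2 Cyp1a1, Tiparp and Cyp1b1 did, which follows from their having been picked for high values in replicate 1 and is no further evidence.

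Of other genes that macrophages carry, also picked singly and not tested as a group, Gpnmb stood at 7.74 and 0 in isotype libraries and at 88.5 and 98.1 in anti-CD226 libraries. Clec4n stood at 2.21 and 6.95 against 25.7 and 62.8, Ccl6 at 6.63 and 0.773 against 22.7 and 119, and Ccl9 at 6.63 and 0 against 20.6 and 55.1 (limma, adjusted p = 0.98 for each of the 4). The 5 genes of the fixed list under the filter went different ways. Itgam stood at 1.11 and 0 against 19.6 and 18.7, Mpeg1 at 0 and 0 against 4.12 and 16.5, Adgre1 at 2.21 and 7.73 against 7.21 and 2.20, Cd14 at 4.42 and 3.09 against 2.06 and 6.61, and Csf1r at 2.21 and 1.90 against 1.03 and 2.62.

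The count of 308 genes at an unadjusted p below 0.05 was matched or passed by 2 of the 3 splits of the 4 libraries, the real one included. The 3 splits are too few for a share under 0.05. The highest other split, isotype replicate 1 and anti-CD226 replicate 2 against the rest, gave 1781, several times the real count. That points to a structure of the samples beside the treatment. With the length trend removed that split gave 1472 and the real split 332. Replicate 1 against replicate 2 gave 124 before the removal.

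Lower ribosomal protein and oxidative phosphorylation genes in the anti-CD226 group were weighed against the trend with transcript length and against a difference of a single library. With the length trend removed, the medians went from -0.33 to -0.22 for ribosomal proteins and from -0.21 to -0.12 for oxidative phosphorylation. Part of each shift thus went with the trend and part stayed. Camera with the preset correlation still called both (adjusted p = 5.2e-11 and 7.8e-04). With an estimated correlation camera called neither even before the removal (adjusted p = 0.91 for each), so whether the trend is the whole cause was not settled. In anti-CD226 replicate 1 the medians against the isotype mean were 0.105 and 0.0928, and in replicate 2 -0.75 and -0.53, where the isotype libraries differed by 0.32 and 0.22. A difference of anti-CD226 replicate 2 alone is a candidate explanation, but these medians restate the pattern and are no separate support for it. Whether it came from its cells or its preparation stays open.

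Higher macrophage genes in the anti-CD226 libraries may be RNA from macrophages left in a sort for ILC2s, a gate meant to remove them, or an effect of the antibody on such cells or on ILC2s, which was not tested. Of the 11 genes of the fixed list in the table, 8 were above both isotype libraries in replicate 2 and 5 in replicate 1, where chance gives 3.67. Ctss was above 190 in every library, and Csf1r, Cd14 and Adgre1 had at most 10 reads in any library. Csf1r counted as above in replicate 2 at 2.62 against 2.21 and 1.90. Such genes could not show RNA from a few macrophages, so these counts cannot decide on it. The abundant Chil3 and Lyz2 stood at 784 and 51.8 in replicate 2, but in replicate 1 Chil3, at 16.5, was no higher than in isotype replicate 1, and Mmp12 was 10.2 times Chil3 against 0.865 times in replicate 2. With few reads for most of these genes, RNA from macrophages and an effect of the antibody cannot be told apart. Removing the length trend took the median difference from the isotype mean in replicate 2 from 0.77 to 1.03 over all 11 genes, and from 0.999 to 1.24 over the 6 above the filter, against that trend as the cause.

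Lower Il9 may be a response of ILC2s to anti-CD226, as a hypothesis from 2 libraries per group that failed the adjustment over all genes. With the length trend removed its log2 fold change was -1.95 with a standard error of 0.33 (limma, adjusted p = 0.98). In the decile of shortest transcripts the median deviation of a library lay between -0.23 and 0.15, so the trend is too small to account for it. Fewer mast cells or basophils, which also transcribe Il9, would lower their own genes. The 8 genes tested of that list other than Kit, which ILC2s carry too, had a median of -0.27, against -2.10 for Il9. The standard error of that median, 0.32, treats genes as replicates, and the list pools mast cells with basophils. Cpa3 and Mcpt8 were lower, by less than Il9 (log2 fold change -0.90 and -0.98), and Gata2 was higher (1.24). Fewer mast cells or basophils therefore cannot be set aside. Chance among 13010 genes stays open.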
